A study of Mus musculus with 8 samples.

How the data were processed

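RRBS libraries came from nephron progenitors sorted from kidneys of CD1 mouse embryos at stage E17.5, with 4 libraries from calorie-restricted and 4 from unrestricted dams. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, embryos of both sexes were used and samples were spread over several sequencing lanes, but the lane of each library was not given in the sources used here.

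The submitters' processing notes name Trim Galore 0.3.3, cutadapt, FastQC, Bismark 0.13.1, methylKit and the genome build mm10, with no order or settings. The deposited files hold, for every CpG cytosine on its strand, the count of reads covering it and the percent of those reads called methylated and unmethylated. Their layout is that of methylKit's text format. The lowest deposited count was 1 read, so no coverage minimum had been applied in the files. Methylated reads were recovered as count times percent and rounded, and up to 1000 reads per cytosine the product lay within 0.0488 of a whole number in every library. The strands of each CpG were then added. No spike-in was used here as a check of bisulfite conversion. Reads at mitochondrial CpGs, which are normally unmethylated, were called methylated in 0.0221 to 0.0854% of cases per library (upper limits of the exact 95% binomial intervals 0.0642 to 0.157%). Binomial intervals cover counting error only, since PCR copies in RRBS cannot be removed.

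Depth ranged from 16045992 to 37305007 reads per library, and between 585106 and 1005919 autosomal CpGs per library had at least 10 reads. The analysis used the 441994 autosomal CpGs with at least 10 reads in all 8 libraries. The median CpG had 20 to 44 reads per library, so levels of single CpGs carry more counting error than those of tiles. Units were 1 kb tiles with at least 3 such CpGs, single CpGs, and gene-end windows. Units without any methylated or any unmethylated read were not tested, which left 33897 tiles, 191637 CpGs and 10933 windows.

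No genome sequence or gene structure was used. Gene positions came from a RefSeq table of the assembly GRCm38.p6, the coordinate system of mm10, which holds no strand and no exons. The planned promoters could therefore not be placed at the 5' end. For each protein-coding or lncRNA gene, the 1.5 kb window (1000 bp outside and 500 bp inside the gene) at the end with more CpGs in the data was used instead, and genes with a tie were left out. Of these 10933 windows 94.1% had a level below 20%, against 65.3% of the 874 windows that could be tested at the other end. These sets differ in genes and, by the choice of end, in CpG number, so the contrast does not show that the chosen ends are promoters. Tiles were assigned to genes whose body, extended by 5 kb at both ends, they overlap. Exons, introns, CpG islands and repeats were not analysed here.

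The main model was a logistic regression of methylated on total reads with 1 term for diet, fitted to the 8 libraries. The likelihood-ratio F test used a Pearson dispersion moderated across units by a Python port of limma's squeezeVar and not allowed under 1. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was a call. Levels per group are means of 4 library levels with their SD, and differences are restricted minus unrestricted in percentage points. Single values per library were compared by exact two-sided permutation over the 70 labelled splits of the libraries, whose smallest p is 0.0286. Gene lists were tested with camera (preset correlation 0.01, and an estimated one) and fry of limma 3.58.1 on M-values, log2((methylated + 1)/(unmethylated + 1)). They covered nephron progenitor identity, early nephron differentiation, ureteric bud, stroma, podocyte, tubule, endothelium, blood, DNA methylation machinery, one-carbon metabolism, nutrient and insulin sensing, glycolysis, Wnt signalling, Hox genes, imprinted genes and germline genes. Of 481 entries in the 16 lists, 8 had no match in the gene table.

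Groups, tests, lists, 54 alternatives and the rule for named genes were chosen before the data were examined. By that rule, up to 10 called tiles of largest difference per direction are named, with 5 called windows of smallest p per direction, 3 called CpGs of smallest p, the 3 members of smallest p per list, and Dnmt1, Dnmt3a, Six2, Cited1, Eya1, Pax2, Wt1, H19, Snrpn and Kcnq1ot1 whatever their p. Gene models named Gm or ending in Rik were passed over where another gene could be given. Of the list members that this rule names, 2 are not reported here. Alternatives included limma and edgeR 4.0.16 tests, a fixed dispersion, other coverage minimums, tile sizes and windows, covariates, the replicate number as a block, and leaving out each library. After the data were seen, 22 alternatives were added, among them leaving out both restricted libraries whose reads leaned to unmethylated CpGs.

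The models were tested on simulated data with the real depths and 200 changed units. Changed units were drawn only from those of intermediate level, above 20%, and all units of a kind shared 1 overdispersion. The shares recovered therefore do not describe units of low level, which most windows are, and real dispersion can differ between units. At a change of 20 points the main model recovered 98.0% of changed tiles, 24.5% of CpGs and 99.0% of windows, and at 10 points 34.5%, 1.5% and 59.0%. Of its calls, 9.68% of tiles, 34.7% of CpGs and 5.26% of windows were false at 20 points, and 9.21%, 84.2% and 2.48% at 10 points, so calls of single CpGs hold the largest share of false ones, as few changed CpGs were recovered. Of the unchanged units, 5.67 to 6.27% had an unadjusted p under 0.05, slightly more than the nominal share. On simulated sets of 33897 tiles limma recovered 89.0% and edgeR 96.5% at 20 points, and 0% and 23.0% at 10 points. Fits with a covariate or block at first recovered 0 changed units. The pull of sparse units, which these models fit exactly, on the dispersion prior was taken as the cause. In those fits the prior was then estimated from units with at least 40 methylated and 40 unmethylated reads, a choice made after the data were seen, and the main model was also run with that prior. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.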

Results

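Genomic DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which reads the CpG-rich part of the genome after a restriction digest. The cells were mouse nephron progenitors, the renal stem cell pool that expresses the transcription factor Six2 and is used up as nephrons form. They were sorted by a Six2-driven green fluorescent reporter from kidneys of outbred CD1 embryos at stage E17.5. Dams received either 70% of the average daily food intake or unrestricted food during pregnancy, and each of these 2 groups had 4 libraries. The comparison asked whether maternal calorie restriction altered DNA methylation of these progenitors. The labels do not say whether a library was 1 litter or a pool, so the p-values measure only the spread between these 8 libraries. Sequencing depth, as the sum of reads over CpG cytosines, ranged from 16045992 (restricted library 2) to 32054622 reads (library 1) in the restricted group and from 20863822 (library 3) to 37305007 reads (library 2) in the unrestricted group (exact permutation p = 0.20). The 441994 autosomal CpGs covered by at least 10 reads in every library were compared, with a median of 20 to 44 reads per CpG and library.

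Mean CpG methylation of the progenitors was nearly equal in both diet groups, at 16.2% ± 0.128 with restriction and 16.2% ± 0.105 without (SD, n = 4 each). The difference was -0.0569 percentage points (exact two-sided permutation test, p = 0.543). CpGs in windows at gene ends were nearly unmethylated in both groups, at 1.75% ± 0.0409 and 1.78% ± 0.0337. CpGs inside genes but outside those windows averaged 22% ± 0.182 and 22.1% ± 0.148, and intergenic CpGs 50.3% ± 0.295 and 50.4% ± 0.228. CpGs of intermediate level (20 to 80%) showed the largest mean difference of the 6 compartments, -0.773 points, which was within the spread of the libraries (exact permutation p = 0.40, adjusted p = 0.891) and ranged from -1.04 to -0.239 points without 1 library. The lowest adjusted p of the 6 compartments was 0.891. When each library was averaged over its own CpGs of at least 10 reads, the restricted mean was 23.3% ± 5.12 and the unrestricted mean 29.8% ± 1.36 (exact permutation p = 0.0286), with 24.5%, 16.1%, 28.3% and 24.3% in restricted libraries 1 to 4 and 28.7 to 31.7% in the unrestricted ones. On the shared CpGs, reads of restricted libraries 1 and 2 leaned to unmethylated CpGs: their read-weighted mean minus their unweighted mean was -2.24 and -3.28 points, against -0.575 to 0.817 points in the other 6 libraries. Without both, or without restricted library 2 alone, the difference over shared CpGs turned to 0.0303 and 0.00412 points.

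**Figure D1:**
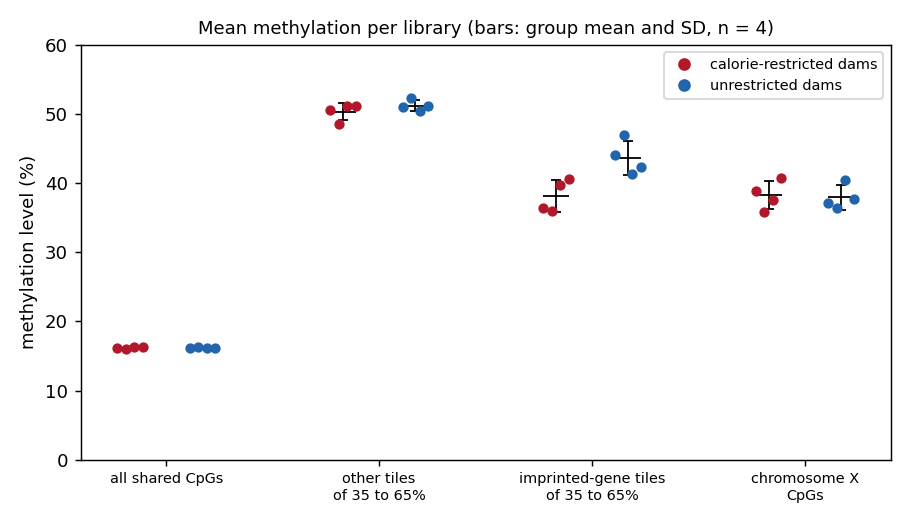
Mean methylation level in percent (vertical axis) of each library for all shared autosomal CpGs, other tiles and imprinted-gene tiles of 35 to 65%, and chromosome X CpGs; points are libraries, bars the group mean and SD (n = 4). The groups overlap except at the 22 imprinted-gene tiles, where the restricted mean is 38.2% and the unrestricted mean 43.7%.

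Among 33897 tested 1 kb tiles, 6 passed the test, of which 5 were lower and 1 higher with maternal restriction. The tile in Zc3h7a, which encodes a CCCH zinc finger protein, rose from 9.71% ± 1.34 to 20.8% ± 4.45 (chromosome 16, 11144001 to 11145000; 16 CpGs; adjusted p = 0.0111). It was very deeply covered, with 2564 to 16451 reads per library. Tiles in 2 imprinted genes fell. Zrsr1, a retrogene of a splicing factor that lies inside Commd1, went from 50.4% ± 3.29 to 30.7% ± 4.99 (chromosome 11, 22974001 to 22975000; 5 CpGs; adjusted p = 0.0411). Gnas, which encodes the stimulatory G protein alpha subunit, went from 48.4% ± 4.87 to 29.1% ± 3.80 (chromosome 2, 174327001 to 174328000; 8 CpGs; adjusted p = 0.0370). The tile in Ntrk2, the receptor of brain-derived neurotrophic factor, fell from 29.5% ± 3.89 to 14.6% ± 3.36 (chromosome 13, 59074001 to 59075000; 7 CpGs). The tile in Caly, which encodes the vesicle protein calcyon, fell from 41.1% ± 2.69 to 26.4% ± 4.81 (chromosome 7, 140070001 to 140071000; 9 CpGs; adjusted p = 0.0411 for both). The remaining tile, in the gene model 4833420G17Rik (chromosome 13, 119462001 to 119463000; 13 CpGs), was at 0% in every restricted library and at 3.94% ± 2.87 in the unrestricted group, where 1 library was also at 0%. At the first 5 of these tiles, all 4 restricted libraries lay on one side of all 4 unrestricted ones, and 77 to 16451 reads stood behind each library's value.

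The count of tiles depended on the test and on single libraries: limma on M-values called 0 tiles (2075 at an unadjusted p under 0.05), edgeR's quasi-likelihood test called 110, and the logistic model with its dispersion prior taken from well covered tiles called 0 (1702 at an unadjusted p under 0.05), against 6 (2141). Without restricted library 2, 3 or 4 it called 1, 24 and 2 tiles, without unrestricted library 2, 3 or 4 it called 20, 2 and 0, and without restricted libraries 1 and 2 it called 4, all higher. The Zc3h7a tile lost its call only without unrestricted library 4 among the 8 fits that left out 1 library (difference 10.7 points, adjusted p = 0.0685), but it could not be tested without the CpGs of highest coverage, where all 5 called tiles were lower. The Gnas and Caly tiles kept theirs in 4 of the 8 fits, the Ntrk2 tile and the 4833420G17Rik tile in 3, and the Zrsr1 tile in 2, with a highest adjusted p of 0.181, reached by the Ntrk2 tile. Where these calls were lost the differences stayed at -17.6 to -20.5 points for Gnas, -13.3 to -14.6 for Caly, -14.1 to -16.1 for Ntrk2, -2.98 to -3.94 for 4833420G17Rik and -18.3 to -20.2 for Zrsr1.

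**Figure D2:**
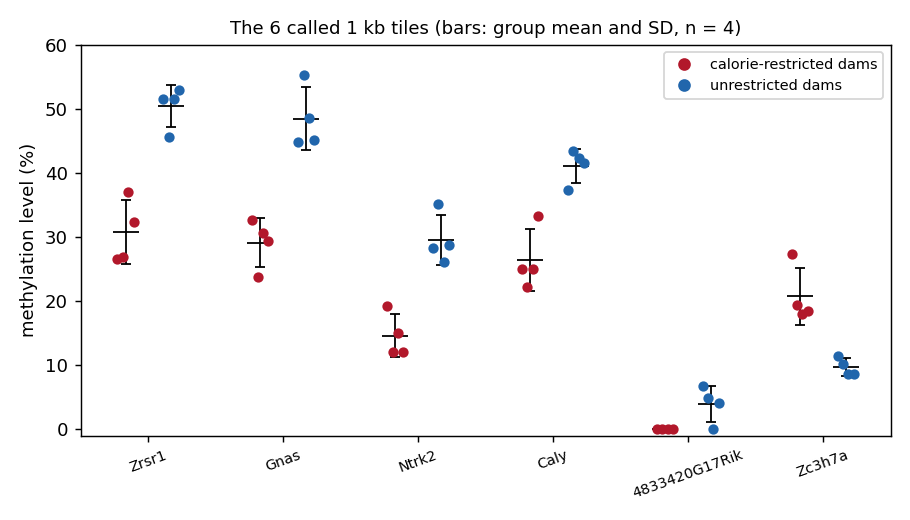
Methylation level in percent (vertical axis) of each library at the 6 called tiles, named by gene; points are libraries, bars the group mean and SD (n = 4). At Zrsr1, Gnas, Ntrk2 and Caly all restricted libraries lie below all unrestricted ones, and at Zc3h7a above them.

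At gene ends, 9 of 10933 windows of 1.5 kb passed the test, 8 lower and 1 higher with restriction. Phgdh, the enzyme that commits glycolytic carbon to serine synthesis, fell from 5.36% ± 1.91 to 1.17% ± 1.05 (chromosome 3, 98339470 to 98340969; 13 CpGs; adjusted p = 0.0109). Vamp9 fell from 33.4% ± 6.85 to 16.6% ± 2.39 (chromosome 5, 99905242 to 99906741; 13 CpGs; adjusted p = 0.00965). Yif1b, a membrane protein of transport from the endoplasmic reticulum to the Golgi, fell from 61.3% ± 1.41 to 51.5% ± 3.18 (chromosome 7, 29247033 to 29248532; 15 CpGs; adjusted p = 0.0109). Nfkbia, the inhibitor of NF-kappa-B, fell from 10.0% ± 1.57 to 6.04% ± 0.645 (chromosome 12, 55492148 to 55493647; 21 CpGs shared with a lncRNA model; adjusted p = 0.0363). The imprinted gene Nap1l5 fell from 44.1% ± 4.75 to 30.1% ± 7.74 (chromosome 6, 58906627 to 58908126; 15 CpGs; adjusted p = 0.0373). All 4 restricted libraries lay below all 4 unrestricted ones at each of these genes except Nap1l5, where 3 did. Windows of 2 further lncRNA models held the CpGs of the Gnas and Ntrk2 tiles (adjusted p = 0.00278 and 0.00505). The only higher window belonged to the gene model 6330409D20Rik (0.147% ± 0.195 to 1.95% ± 1.47). Since the gene table gave no strand, each window was placed at the gene end richer in CpGs, and it need not be the promoter.

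No gene-end window passed with limma (740 at an unadjusted p under 0.05), with the dispersion prior taken from well covered windows (405, against 746) or with chromosome Y coverage as a covariate (486). With edgeR 12 were called, but only 2 of them were among the 9 of the main model. Without restricted library 3 there were 32 calls, without unrestricted library 2 there were 18, and without restricted libraries 1 and 2 there were 6, of which 4 were higher. Phgdh and Vamp9 kept their calls in each of the 8 fits without 1 library. So did the lncRNA windows that hold the CpGs of the Gnas and Ntrk2 tiles (highest adjusted p = 0.0150 and 0.0326). Tested as tiles, these same CpGs kept their calls in only 4 and 3 of the 8 fits. Yif1b lost its call without restricted library 1 (-8.68 points, adjusted p = 0.114). Nap1l5 lost its call without restricted library 1, 2 or 4 or unrestricted library 1 or 4 (-11.8 to -14.3 points, adjusted p of 0.0517 to 0.153). Nfkbia lost it without restricted library 1 or 2 or unrestricted library 1, 3 or 4 (-3.21 to -4.14 points, adjusted p of 0.0629 to 0.165). Over CpGs of at least 20 reads, the difference at the Nfkbia gene end was -0.00167 points (adjusted p = 0.981).

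**Figure D3:**
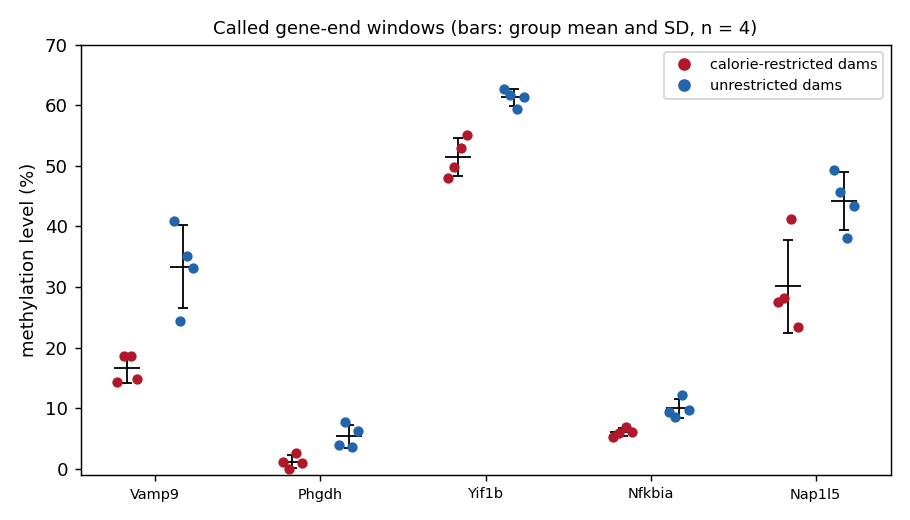
Methylation level in percent (vertical axis) of each library at 5 called gene-end windows; points are libraries, bars the group mean and SD (n = 4). The restricted means lie below the unrestricted ones, from 1.17% against 5.36% at Phgdh to 51.5% against 61.3% at Yif1b.

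At single CpGs, 191 of 191637 tested sites passed, 141 higher and 50 lower with restriction. Of these, 67 lay within 5 kb of the 18S ribosomal RNA gene copy on chromosome 17 (39846354 to 39848202), to which reads of its many copies can align, and 66 of the 67 were higher. Outside it, 75 sites were higher and 49 lower. The higher ones included 16 CpGs in Zc3h7a, 9 in Filip1l and 9 in a lncRNA model on chromosome 11. Each of these clusters lay in a short, deeply covered stretch. Whether reads of several copies align there too was not tested. Fitted without the CpGs near the ribosomal copy, 177 sites passed, 104 higher and 73 lower. The 3 sites of smallest p were all higher in all 4 restricted libraries. The CpG at 39845967 of chromosome 17, next to that ribosomal copy, had 8.33% ± 2.41 in the unrestricted and 25.2% ± 4.97 in the restricted group (133 to 691 reads; adjusted p = 1.40e-08). The other two lay in Zc3h7a, at 11144072 (15.3% ± 1.10 and 28.9% ± 4.21; adjusted p = 1.40e-08) and 11144062 (14.5% ± 1.86 and 28.1% ± 4.03; adjusted p = 3.18e-08). All 443 shared CpGs near the ribosomal copy averaged 9.63% ± 2.47 and 12.8% ± 3.23 (exact permutation p = 0.143).

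The count of CpGs was 2 with limma, 92 with edgeR, 8 with the dispersion prior taken from well covered CpGs, and 673 without restricted libraries 1 and 2. Leaving out restricted library 1, 2, 3 or 4 gave 507, 511, 416 and 292 calls, and leaving out unrestricted library 2 gave 746, whereas the 3 named CpGs kept their calls in each of the 8 fits without 1 library. These 3 CpGs are among those of highest coverage, without which 117 CpGs were called, 54 higher and 63 lower.

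Of 16 gene lists on kidney development, nutrition and epigenetic control, the imprinted genes were the only list to pass limma's camera at a preset correlation of 0.01, lower with restriction, and they no longer passed with an estimated correlation (adjusted p = 0.0941 for windows and 0.228 for tiles). In 24 measured windows of imprinted genes the mean level was 24.9% ± 2.70 in the unrestricted and 20.5% ± 3.24 in the restricted group (camera, adjusted p = 0.000621), and in their 91 tiles 31.3% ± 1.20 and 28.2% ± 2.16 (camera, adjusted p = 0.000536). By exact permutation of the list's mean level, p was 0.114 for windows and 0.0571 for tiles. Of the windows 1, Nap1l5, was called over all genes. Adjusted over the list alone, 6 windows were lower and 0 higher: Nap1l5, Mcts2 (38.9% ± 3.41 to 28.8% ± 6.92), Zrsr1 (39.7% ± 4.17 to 31.6% ± 1.95), Peg10 and Sgce with the same CpGs (40.4% ± 12.8 to 25% ± 9.43), and Phlda2 (1.10% ± 1.32 to 0%). Among the tiles, 2 were called, and 6 were lower when adjusted over the list alone, in Gnas, Zrsr1, Nap1l5, Mest, H13 and Inpp5f. The Nap1l5 tile held the same CpGs as the Nap1l5 window, but was not called over all tiles (adjusted p = 0.229). The H13 tile overlapped the Mcts2 window. Tiles and windows of this list are therefore not separate support. In fry, which asks whether the members move one way on balance, the list's adjusted p was 0.470 and 0.322. Its window call was also lost without restricted library 2 (adjusted p = 0.0703) and without restricted libraries 1 and 2 (adjusted p = 0.145).

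Imprinted control regions carry methylation on 1 parental copy and so lie near the middle of the scale. The tiles below were picked by level alone among those in or within 5 kb of listed genes, so they need not be control regions. Listed genes also had tiles of lower mean level that were left out, as in Mest (29.3%) and Peg10 (32.7%). The 22 imprinted-gene tiles with a mean level of 35 to 65% averaged 43.7% ± 2.49 in the unrestricted and 38.2% ± 2.32 in the restricted group, with 16 of the 22 lower. The difference of -5.49 points had an exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow. The 4 imprinted gene-end windows in that range averaged 43.7% ± 4.31 and 35% ± 2.85 (exact permutation p = 0.0571), a difference of -8.65 points that stayed between -10.7 and -7.37 without 1 library. The other 2198 tiles of 35 to 65% averaged 51.2% ± 0.787 and 50.3% ± 1.24 (exact permutation p = 0.429). Across the 8 libraries the imprinted level rose with the read-weighted minus unweighted methylation (Pearson r = 0.897, permutation p = 0.00273, adjusted p = 0.00546 over 4 relations; Spearman rho = 0.81, permutation p = 0.0218, adjusted p = 0.0290). Restricted libraries 1 and 2 had the lowest imprinted levels, 36.4% and 36.0%, and without both, which lie farthest out, r was 0.779. The other tiles of 35 to 65% also followed the lean by Pearson's r (0.839, permutation p = 0.00873, adjusted p = 0.0116) but not by rank (rho = 0.571, permutation p = 0.151, adjusted p = 0.151), and without restricted libraries 1 and 2 their r was 0.525. Without these libraries, the difference of the 22 imprinted-gene tiles was -3.50 points (exact permutation p = 0.133, the smallest that 2 against 4 libraries allow).

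**Figure D4:**
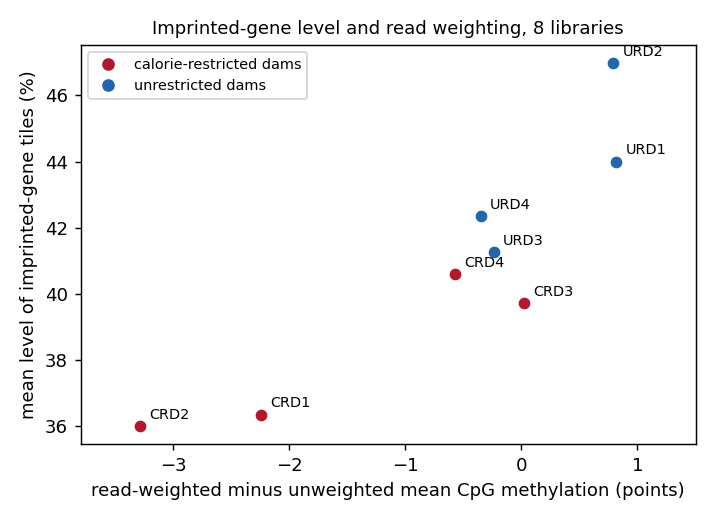
Mean level in percent of the 22 imprinted-gene tiles (vertical axis) against the read-weighted minus unweighted mean CpG methylation in percentage points (horizontal axis); each point is 1 of the 8 libraries, named CRD for restricted and URD for unrestricted dams. Restricted libraries 1 and 2 lie lowest on both axes, at 36.4% and 36.0%.

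Genes that define nephron progenitors were unmethylated at their gene ends in both diet groups. The 18 measured windows of that list averaged 0.0936% ± 0.0427 and 0.0862% ± 0.0570 (unrestricted and restricted; SD, n = 4 each), with 0 called. The Six2 window (41 CpGs, 1582 to 3233 reads per library) was at 0.0599% ± 0.0752 and 0.0728% ± 0.0217. Those of Pax2 (0.0289% ± 0.0579 and 0.101% ± 0.122) and Wt1 (0.0550% ± 0.0635 and 0%) were as low, and of 7 tiles in Six2 the one of smallest p had 27.6% ± 1.13 and 24.2% ± 1.81 (adjusted p = 0.773). Cited1 and Eya1 were not tested, the first being on chromosome X. Fgfr1 and Wt1 were among the members of smallest p. Early nephron differentiation genes (23 windows, with Fgf8 and Bmp2 among those of smallest p) averaged 0.105% ± 0.0174 and 0.147% ± 0.0555, again with 0 called.

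Metabolic lists had few differences. Of 18 one-carbon windows (2.42% ± 0.388 and 2.02% ± 0.419) only Phgdh was called, over all genes and adjusted over the list alone, with Psat1 (10.7% ± 3.82 and 8.55% ± 2.58) and Mat2b next. Of 13 glycolysis windows (3.22% ± 0.412 and 3.05% ± 0.497) 0 were called over all genes, and Pfkp, a phosphofructokinase, fell from 2.54% ± 0.741 to 0.936% ± 0.514 when adjusted over the list alone (adjusted p = 0.00309), followed by Slc16a1 and Pfkl. The 25 nutrient and insulin sensing windows (0.412% ± 0.0717 and 0.401% ± 0.103; Igf1r, Ddit4 and Atf4 first by p) had 0 calls. So had the 10 windows of the DNA methylation machinery (8.32% ± 0.196 and 8.63% ± 0.519; Mbd1, Tdg and Gadd45a). Tiles of smallest p in Dnmt1 (83.8% ± 2.71 and 86.4% ± 0.980) and Dnmt3a (0% and 0.391% ± 0.781), the maintenance and a de novo methyltransferase, had adjusted p = 0.773.

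Lists of signalling and of other kidney cell types had 0 called windows, both over all genes and adjusted over the list alone. The 39 Wnt windows averaged 1.05% ± 0.159 and 0.941% ± 0.142 (Lrp5, Wnt10b and Znrf3 first by p), and the 28 Hox windows 1.85% ± 0.373 and 1.67% ± 0.303 (Hoxa3, Hoxc9 and Hoxc12). The 15 ureteric bud windows averaged 1.07% ± 0.117 and 1.07% ± 0.376 (Wnt11, Sox8 and Spry1), and the 10 stromal ones 0.940% ± 0.210 and 0.760% ± 0.242 (Col1a2, Pdgfrb and Pdgfra). The 11 podocyte windows averaged 0.210% ± 0.142 and 0.204% ± 0.13 (Plce1, Cd2ap and Nes), and the 2 tubule windows, of Lrp2 and Ass1, 0.274% ± 0.0509 and 0.370% ± 0.0242. The 8 endothelial windows averaged 1.04% ± 0.111 and 1.04% ± 0.143 (Sox17, Cldn5 and Fli1), and the 3 of blood, in Tal1, Coro1a and Epor, 1.27% ± 0.390 and 1.21% ± 0.615. Germline genes, which are silenced in somatic cells, were the most methylated list, at 69.9% ± 1.12 and 70.4% ± 0.794 over 9 windows (Smc1b, Mael and Asz1). The smallest adjusted p of camera among the 15 lists other than imprinted genes was 0.619 for windows and 0.638 for tiles. By exact permutation of a list's mean level, not adjusted over the lists, the tubule windows and the tiles of the ureteric bud and one-carbon lists also reached p = 0.0286. Mean, median and camera direction did not share 1 sign for 7 of the 16 lists in windows and for 8 in tiles.

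Tiles and windows of the imprinted genes named in advance did not pass singly. H19, the maternally expressed growth-suppressing RNA, had 70.5% ± 3.27 in the unrestricted and 62.9% ± 2.38 in the restricted group over 3 CpGs (adjusted p = 0.675). The Snrpn tile had 36.6% ± 13.1 and 26.7% ± 13.2, and the Kcnq1ot1 tile 12.8% ± 11.5 and 3.83% ± 5.55 (adjusted p = 0.773 for both). A single CpG in Snrpn (chromosome 7, 60172304; 11 to 47 reads), chosen after its values were seen, was called higher, at 6.05% ± 4.91 and 42.1% ± 30.1 (adjusted p = 0.00205), with 3 of 4 restricted libraries above all unrestricted ones and the fourth at 0%.

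With fewer than 20 called tiles, the 2141 tiles with an unadjusted p under 0.05, which do not pass, were described by level. They made up 8.68% of the 5314 tiles of intermediate level (odds ratio 1.52; Fisher's exact test, p = 1.43e-13), 6.22% of the 20623 tiles below 20% (odds ratio 0.958; p = 0.348) and 5.0% of the 7960 tiles over 80% (odds ratio 0.731; p = 1.67e-08). Neighbouring tiles are not independent, so these p-values are too small. They take tiles as replicates and were not set against other splits of the libraries. Whether the test finds differences more readily at some levels was not tested. A concentration of diet differences at intermediate level is therefore not shown. At intermediate level 324 were lower and 137 higher with restriction, whereas below 20% 600 were lower and 682 higher. Over all levels 52.5% were lower (exact permutation p = 0.743).

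Intermediate tiles varied more between the restricted libraries (median SD 5.15 points) than between the unrestricted ones (4.30 points). The median log2 ratio was 0.29 (exact permutation p = 0.0571), and it fell to 0.10 without restricted library 2. After the sampling variance of the reads was subtracted it was 0.30 (exact permutation p = 0.0286). Diet group accounted for 15.4% of the variance of the 10000 most variable tiles, where splits with equal spread average 14.3% (exact permutation p = 0.0857). Without restricted library 1 or 3 the share was 19% and 19.7%, where splits of 7 libraries with equal spread average 16.7% (exact permutation p = 0.0286 for both). The first 2 principal components, with 22.8% and 17.7% of the variance, set restricted library 2 and restricted library 4 apart from the rest.

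Both sexes were present in the embryos used. Chromosome Y reads numbered 150 ± 35.5 per 100000 autosomal reads in the unrestricted and 130.3 ± 14.8 in the restricted group (exact permutation p = 0.371), a difference of -20.0 that ranged from -33.4 to -4.83 without 1 library. Chromosome Y CpGs with reads numbered 5640 ± 876 and 4519 ± 608 (exact permutation p = 0.114). Such a count can also rise with sequencing depth, which differed between the libraries. Methylation of 7925 chromosome X CpGs averaged 37.9% ± 1.82 and 38.2% ± 2.03 (exact permutation p = 0.83). None of these 3 measures of the mix of sexes passed its test.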

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

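The tests of read lean, depth and other intermediate tiles at imprinted genes, and the counts over other splits for tiles, CpGs and gene lists, were chosen after their results were seen.

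In 3 cases a value stood apart from the rest of its group, by a gap to the nearest library above Dixon's 95% critical value for 4 samples. Chance gives about 1 in 20 such groups, and 72 groups were examined. Unrestricted library 2 had 1.83% methylation over gene-end window CpGs, against 1.76 to 1.77% in the others. It also had 0.796% over CpGs below 20%, against 0.740 to 0.748%. Restricted library 1 had 27.4% at the Zc3h7a tile, against 18 to 19.4% in the other restricted libraries.

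Imprinted-gene tiles of 35 to 65% were 5.49 points lower with restriction. A shift of equal size in all tiles of intermediate level is argued against, since the other 2198 tiles of 35 to 65% differed by -0.873 points. Of 10000 random sets of as many of these tiles, 0% had a mean difference as low (central 95% of the sets -2.91 to 1.12 points). The sets take tiles as independent, whereas several imprinted tiles lie in the same gene, so this range can be too narrow. Read depth stays open, since within the groups the imprinted level had r = 0.226 with log10 reads (exact permutation p = 0.613), which 8 libraries leave too wide to decide. A bias of the libraries against methylated fragments remains a candidate explanation, since within the groups the level rose with the read-weighted minus unweighted methylation (r = 0.817, exact permutation p = 0.0365). Removing that slope takes the difference from -5.49 to -2.49 points. An effect of maternal diet stays open too and is not tested apart from this bias, since the libraries with the strongest lean are both restricted.

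CpGs near the 18S ribosomal RNA gene copy supplied 66 of the 141 CpGs called higher with restriction. A change in the number of ribosomal DNA reads, and so in which of the many copies are read, and an effect of diet cannot be told apart here. Within the groups the level over these CpGs had r = 0.669 with their share of reads (exact permutation p = 0.104), too few libraries to decide. Across all 8 libraries, diet groups pooled, r was 0.753 (permutation p = 0.0456, adjusted p = 0.0456 over 4 relations) and rho 0.833 (permutation p = 0.0154, adjusted p = 0.0290), and r was 0.669 without the 2 libraries farthest from the median share.

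The 124 called CpGs outside the ribosomal copy may include sites where outbred CD1 mice carry variants against the reference, which would leave neighbouring CpGs unmoved. Of the 124, 96 (77.4%) had at least 2 tested CpGs within 100 bp, under the 80% such a check needs, and the median ratio of the neighbours' mean difference to the called CpG's own was 0.677 (quartiles 0.137 and 0.936). The ratio was under 0.25 at 30 sites and over 0.75 at 43, so the check is void for the set as a whole, and variants and methylation changes cannot be told apart.

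Chance was not excluded as the source of the counts of calls. The diet split gave 6 tiles, and 4 of the 35 splits of the libraries, the diet split included, gave as many, with up to 36 in another split. For CpGs, 4 of the 35 splits gave at least 191, with up to 821. For gene-end windows, 2 of the 35 gave at least 9, with up to 9 in another split. At least 1 gene list passed camera in 8 of the 35 splits over windows (at most 1 in another split) and in 7 over tiles (at most 2). A smallest p as small as that of the diet split came in 2 of the 35 splits over windows and in 1, the diet split itself, over tiles. The split with 36 tiles and 821 CpGs set restricted libraries 1, 3 and 4 with unrestricted library 2 against the rest. It was the largest of the 35 and picked after the counts were seen, so a structure of the samples is possible but not shown. It is the diet split with library 2 of both groups exchanged, so it keeps part of any diet contrast, and what sets it apart was not tested.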

How the results depend on the processing

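The alternatives with restricted libraries 1 and 2 left out, the read lean as a covariate, the prior from well covered units, the other gene end, the ribosomal copy left out, at least 20 reads for imprinted tiles, and the replicates left out for compartments, variability, structure, imprinted genes, lists, level classes and sex chromosomes were chosen after seeing the data. The cause of the changes below was not tested, except where the construction shows it. Windows at every annotated transcript start were not run, since no transcripts were given.

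Called tiles numbered 6. They were 2 with at least 20 reads (1 higher, 1 lower) and 2 with at least 3 libraries per group (2 higher, 0 lower). They were 0 with limma, 110 with edgeR (5 of them among the 6) and 607 without overdispersion. At adjusted p under 0.01 and a difference of at least 25 points they were 0. With a covariate they were 2 for chromosome Y coverage (2 higher, 0 lower), 13 for mean methylation (5 higher, 8 lower) and 5 for the read lean (4 higher and 1 lower, 0 of them among the 6). They were 0 with the prior from well covered tiles, and 0 to 24 without 1 replicate. Called CpGs numbered 191. They were 103 with at least 20 reads, 117 without the CpGs of highest coverage (54 higher, 63 lower), 2 with limma, 92 with edgeR, 696 without overdispersion, 124 with a difference of at least 10 points, 111 on separate strands, 20 with chromosome Y coverage and 294 with the read lean as a covariate, 8 with the prior from well covered CpGs, 673 without restricted libraries 1 and 2, and 134 to 746 without 1 replicate. Without the ribosomal copy they were 177 (104 higher, 73 lower). Called windows numbered 9. They were 14 with at least 20 reads (3 of them among the 9), 0 with limma, 167 without overdispersion and 4 with a difference of at least 10 points. With a covariate they were 0 for chromosome Y coverage, 3 for mean methylation and 0 for the read lean. They were 0 with the prior from well covered windows and 1 at the other gene end, where 874 windows were tested. Without 1 replicate they were 6 to 32.

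Same-numbered libraries did not deviate together (r of -0.0745 to 0.0234, and 1 of 8 libraries was closest to its own number). Pairs of different number had r of -0.0396 to 0.0494. No pairing by number was seen, but a shared batch that leaves no such trace is not excluded. With the replicate block there were 2 tiles, 18 CpGs and 1 window, of which 1, 18 and 0 were among the main calls. These fits and those with covariates also use the other prior, under which the model without a block called 0, 8 and 0.

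The global difference of -0.0569 points was -6.53 over each library's own CpGs, 0.0303 without restricted libraries 1 and 2, and -0.0874 to 0.00412 without 1 replicate. With at least 20 reads, the difference became 2.38e-06 points at intergenic CpGs and 0.00366 below 20%. Without 1 replicate it was -0.124 to 0.00744 within genes, -0.160 to 0.0544 at intergenic CpGs, -0.0403 to 0.00873 below 20% and -0.149 to 0.195 over 80%. The share of lower tiles was 46.1% with at least 20 reads, 48.8% in 300 bp tiles and 48.0 to 56.7% without 1 replicate. At an unadjusted p under 0.05, limma had 776 tiles lower and 1299 higher. Without restricted libraries 1 and 2, 774 were lower and 991 higher, and with the replicate block 861 were lower and 719 higher. Odds ratios were 0.817 below 20% and 0.907 over 80% in 300 bp tiles, and 0.782 to 0.956 below 20% without 1 replicate. The variability ratio was 0.30 after subtraction of sampling variance and 0.10 to 0.41 without 1 replicate, the diet share of variance 16.1 to 19.7% (16.7% for equal spread), and the chromosome X difference -0.483 to 1.18 points.

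The imprinted tile difference was -7.98 points with at least 20 reads (9 tiles; exact permutation p = 0.0571, no longer under 0.05 with all 8 libraries), -3.50 without restricted libraries 1 and 2 and -6.30 to -4.38 without 1 replicate. For this difference no p under 0.05 can be reached with 1 or 2 libraries fewer (the smallest exact permutation p are 0.0571 and 0.133). With an estimated correlation 0 lists passed over windows and 0 over tiles (imprinted adjusted p = 0.0941 and 0.228). Over windows 0 passed without restricted libraries 1 and 2 (adjusted p = 0.145), and 0 to 1 without 1 replicate (8.04e-05 to 0.0703). Of the 18 called features named or counted singly, 18 held without overdispersion, 8 with edgeR, 0 with limma, 3 with the other prior, 3 with the read lean, 4 with chromosome Y coverage and 6 with mean methylation as a covariate, 4 with the replicate block and 6 without restricted libraries 1 and 2, and none reversed. Some of the 18 share CpGs, as the Gnas and Ntrk2 tiles do with lncRNA windows, so they are not 18 independent results. Without the CpGs of highest coverage, the 14 of the 18 that could be tested held. The Zc3h7a tile and the 3 named CpGs could not be tested. At the depth of these libraries, 1.5% of simulated changes of 10 points were recovered at single CpGs of intermediate level. How far depth or the number of tests sets this was not tested.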

Other observations

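The regions and relations in this part were chosen after their values were seen. Outside the ribosomal copy, called CpGs lay in 76 bins of 10 kb, and 4 of these bins held 9 or more. In Zc3h7a, 16 CpGs between 11144050 and 11144121 of chromosome 16 were higher with restriction. In Filip1l, 9 CpGs on chromosome 16 (57391292 to 57391501) were higher, and the one of smallest p had 15.8% ± 3.50 in the unrestricted and 23.1% ± 1.74 in the restricted group (SD, n = 4 each; 561 to 1284 reads; adjusted p = 0.00213). On chromosome 11 (109011776 to 109011918), 9 CpGs in a lncRNA model were higher. These higher clusters lie at deeply covered CpGs, against a median of 20 to 44 reads per CpG and library. Whether reads of several copies align there, as they can near the ribosomal copy, was not tested. In Kcp, which encodes a secreted regulator of bone morphogenetic protein signalling, 11 CpGs on chromosome 6 (29496474 to 29496564) were lower. The CpG of smallest p there, at 29496553, had 34.2% ± 15.9 and 4.69% ± 3.52 (25 to 75 reads; adjusted p = 0.000145), with all 4 restricted libraries below all unrestricted ones. The 1 kb tile that holds these 11 CpGs was not called. CpGs so close can lie on the same reads, so the number of calls in a cluster is not independent support.

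The called Phgdh window rested partly on 2 called CpGs at 98339813 and 98339823 of chromosome 3. The first had 29.8% ± 6.05 in the unrestricted and 9.41% ± 6.94 in the restricted group (16 to 91 reads, adjusted p = 0.0163).

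Methylation of chromosome X CpGs rose with the share of reads on chromosome X over the 8 libraries (Pearson r = 0.982, permutation p = 0.000248, adjusted p = 0.000992; Spearman rho = 0.952, permutation p = 0.00114, adjusted p = 0.00456). Adjustment was over the 4 relations computed across libraries. Without the 2 libraries farthest from the median share, r was 0.938.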
